A study of Homo sapiens with 12 samples.

How the data were processed

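Total RNA from SUM159 cells was labelled with Cy3 and hybridised to 1-colour Agilent human microRNA arrays, per the labels. The array files hold, per the file headers, a total gene signal for each name, an intensity on a linear scale, with its error and a detection flag. They were written by Agilent Feature Extraction 9.1, per the submitters' processing notes. The background settings are not given in the sources used here. Names that were not detected hold an intensity of 0.1 in the deposited files. The deposited series matrix holds log2 values of 221 microRNAs with 0 where a microRNA was not detected, and in 3 further detected cells of 1 array. Its scale follows log2 of the array signal, with the same direction, but its normalization and centring stay unknown. Against the array signal it was shifted by about -0.23 at dim and 0.29 to 0.36 at bright microRNAs on slide 1, and by about 0.28 and -0.28 to -0.23 on slide 2. The column medians ran from 3.19 to 4.06. The label protocol describes an mRNA labelling kit although the features are microRNAs, and the source names of the 2 metformin groups disagree with the titles and characteristics. That of control shRNA with metformin reads untreated and that of Dicer shRNA with metformin reads control, treated. Groups were taken from the titles.

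The array lists 851 human, 88 viral and 22 control names. Of the human names, 11 carry a version suffix, which was dropped to match lists, and the names are those of the array's design. No coordinates are given, because the files name microRNAs only. Replicate pairs were checked for identical values, and their differences exceeded the stated signal error (root mean square z 1.08 to 2.65). The labels call the replicates biological.

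Each array was scaled to its 75th percentile over the 98 human microRNAs detected on all 12 arrays (factors 0.869 to 1.20). Scaled signals under a floor of 3.01 (log2 1.59), the median over arrays of the 5th percentile of detected signals, were set to the floor, and log2 was taken. The 208 microRNAs detected on all 3 arrays of at least 1 group were fitted with 4 group means in limma 3.58.1 (lmFit and eBayes, R 4.3.3), on 8 residual degrees of freedom and a prior of 1.85. A call is a Benjamini-Hochberg adjusted p under 0.05. Groups at the floor have no spread of their own, so errors of microRNAs not detected in some groups are understated. Where all arrays of a group lay at the floor, the fold is given as at least the ratio to, per array, the higher of the floor and the array's lowest detected signal. Such signals belong to other probes, so the bound rests on this floor. Where some arrays of a group lay at the floor, the difference is limited by it, and the text says on how many arrays the microRNA was detected. The results were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and data.table (version 1.17.8), and figures with matplotlib 3.10.9.

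The comparisons were the knockdown within each slide and averaged over both, metformin within each line, and their interaction. The text names the 12 largest changes per direction among calls whose groups do not overlap, and always miR-33a, let-7a, miR-103, miR-107, miR-21, miR-34a, miR-200c, miR-16 and miR-222 where tested. It also names up to 4 members of a list. For the interaction and the average over slides the calls alone counted. Before the data were examined, 14 lists were fixed. They are the let-7 family, the miR-17/92 clusters, MYC-repressed microRNAs, the miR-200 family, p53-linked microRNAs, the group of miR-103, miR-107 and miR-15/16, metabolic, invasion-linked, miR-23/27/24, reclassified, microprocessor-independent, passenger strand, blood cell and other tissue microRNAs. The 10 lists with at least 3 tested members were tested with camera (preset correlation, then an estimated one) and with fry, adjusted over the lists within a comparison.

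The fit was tested on simulated data, in 20 simulations per comparison with 60 changed microRNAs. These were taken from the brighter microRNAs, as many higher as lower, with noise drawn separately for each microRNA. The recovery therefore does not cover dim microRNAs or groups at the floor. No share below covers unbalanced changes or a spread shared between microRNAs. With each microRNA's own spread, changes of 1 log2 were recovered in 75.3% (interaction) to 98.7% (both slides) and changes of 2 log2 in 99.0% to 100%. False calls made up 6.51% (knockdown under vehicle) to 13.6% (both slides) of calls, above the nominal 5%. With spreads drawn at random over microRNAs, the first form of this test, they made up 7.76% (knockdown under vehicle) to 15.8% (both slides). When the true scale factors were used they made up 2.74% to 5.48% under both forms, so the excess came from the error of the estimated scaling. The second form was added after a single run of the first gave a higher share in the metformin comparisons.

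Alternatives covered the scaling (none, 75th percentile over all human names, quantile, median, reclassified entries), the series matrix, an offset of 16 or a floor of 1 in place of the floor, the detection filter, the groups in the fit, an intensity trend, array weights, a replicate block and leaving out each array. The 75th percentile over all human names fell on the value for undetected names, so this setting equals no scaling. Scaling to viral microRNAs was added after seeing the data. The overall signal was tested by exact permutation within lines or slides. Control features were left out of scaling and tests of human microRNAs, and were fitted separately with the same scaling, as were viral microRNAs.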

Results

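MicroRNAs were measured in SUM159 cells, a human triple-negative breast cancer line, that stably carried either a scrambled control shRNA or an shRNA against Dicer, the RNase that cuts microRNA precursors to their mature form. Each line received vehicle (PBS) or 0.5 mM metformin, a drug against type 2 diabetes, for 24 h. Total RNA of 3 biological replicates per group, 12 samples in 4 groups, was hybridised to 1-colour Agilent microRNA arrays. Both vehicle groups lay on slide 1 and both metformin groups on slide 2, so metformin and slide cannot be told apart. The knockdown was compared within a slide. On both slides the control shRNA arrays held the first positions and the Dicer shRNA arrays the next, so line and array position cannot be told apart either. The arrays carry no probe for the Dicer mRNA, so the knockdown itself was not checked here.

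Of 851 human microRNA names, 263 were detected on at least 1 array and 98 on all 12. The arrays detected 130 to 204 human microRNAs. The group means were 187 ± 14.7 (SD, n = 3) in control shRNA cells with vehicle, 161 ± 16.6 (SD, n = 3) in Dicer shRNA cells with vehicle, 158 ± 6.11 (SD, n = 3) in control shRNA cells with metformin and 141 ± 11 (SD, n = 3) in Dicer shRNA cells with metformin. The entry miR-923, since withdrawn as a microRNA, took 77.7% to 84.3% of the summed human signal on each array. No replicate pair shared an identical value, and their log2 signals correlated across microRNAs with r between 0.956 and 0.992. The number of arrays, 3 per group, limits the precision of every value that follows. Names are given without the species prefix hsa-, changes are log2 differences ± SE from limma with 3 arrays per group, and 208 microRNAs were tested. The files hold the same signal for miR-33a and miR-33b* on each of the 12 arrays, so each miR-33a value belongs to the pair.

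The first question was how Dicer shRNA cells differed from control shRNA cells with vehicle. MicroRNAs of several canonical families were lower in Dicer shRNA cells than in control shRNA cells. miR-19a, of the oncogenic miR-17/92 clusters, fell by 4.34 ± 0.10 and was detected on 1 of the 3 Dicer shRNA arrays. miR-103, linked to insulin sensitivity and a regulator of Dicer itself, fell by 3.73 ± 0.31 and let-7a, of the let-7 tumour suppressor family, fell by 3.56 ± 0.40. let-7i was at least 10.3-fold lower, miR-17 at least 8.56-fold, miR-107 at least 7.39-fold and miR-130a at least 6.93-fold, since none of the Dicer shRNA arrays detected them. miR-29b fell by 3.53 ± 0.12, miR-106b by 3.39 ± 0.43, miR-19b by 3.20 ± 0.42, miR-27a by 3.15 ± 0.17 and let-7f by 3.08 ± 0.22. miR-21, an abundant microRNA in many tumours, fell by 2.50 ± 0.27, or 5.66-fold, and miR-222 by 0.69 ± 0.13, though it was 0.118 after quantile normalization. miR-34a, a p53 target, was at least 2.14-fold lower, and miR-33a (0.01 ± 0.22) did not pass. The floor limits the values of miR-103, miR-29b and let-7f, detected on 1 of 3 Dicer shRNA arrays, and of let-7a and miR-106b, detected on 2.

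A smaller set was higher in Dicer shRNA cells with vehicle. miR-520e rose by 1.99 ± 0.31, miR-557 by 1.97 ± 0.24, miR-370 by 1.83 ± 0.24 and miR-1275 by 1.47 ± 0.16, and miR-583 was at least 3.15-fold higher. miR-371-5p, miR-1181, miR-572, miR-564, miR-671-5p, miR-520b and miR-1226* rose by 1.25 to 1.44. The floor limits miR-557, detected on 1 of 3 control shRNA arrays, and miR-520e, miR-370 and miR-371-5p, detected on 2. In total 124 of 208 microRNAs passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 45 higher and 79 lower. Of the 98 detected on all 12 arrays, 40 were higher and 23 lower. The 2 groups did not overlap for 131 of the 208, or 63.0%, where chance gives 10% without a filter. The detection filter keeps some microRNAs only because 1 group is high, so part of this separation is built in. The split moved with the scaling. It was 61 higher and 53 lower after quantile normalization, 32 and 90 after scaling to the median, 64 and 58 after scaling to the reclassified entries, and 14 and 119 after scaling to viral microRNAs.

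By list, all 6 tested let-7 members fell (median -2.66), as did all 10 tested members of the miR-17/92 clusters (median -2.33) and all 5 of the group of miR-103, miR-107 and miR-15/16 (median -2.57). Of 16 MYC-repressed microRNAs outside let-7, 15 fell (median -1.78), among them miR-29b and miR-16, which was at least 4.71-fold lower. Of 6 members of the miR-23/27/24 clusters 5 fell, and all 5 invasion-linked microRNAs fell, miR-21 and miR-146a the most. With undetected members at their bounds, the miR-17/92 median was -2.28 and the other medians given were the same. The median of each of the 6 lists stayed below 0 under each scaling. Camera called these 6 lists lower against the other microRNAs (adjusted p 7.7e-05 to 0.041), and with an estimated correlation the adjusted p was 0.24 to 0.30, so no call held. Of 16 microprocessor-independent microRNAs, which are cut from short introns or otherwise bypass Drosha, 7 rose and none fell. Their median was 0.43, or -0.29 after scaling to viral microRNAs. Camera gave an adjusted p of 0.0071 for this list, and adjusted p = 0.40 with an estimated correlation. Adjusted over the list alone, the counts were the same for the let-7, miR-17/92, MYC-repressed, miR-103, miR-23/27/24 and invasion-linked lists, and 5 higher for the microprocessor-independent list. The 4 control features named hur, which are not in the microRNA set, changed by a median of -0.81, and 3 of them were lower. The 10 viral microRNA probes detected on all arrays had a median change of 0.87, and 8 were higher. The hur features thus moved with the falling lists and the viral probes with the rising one. A loss of signal shared with the hur features, or unspecific signal, stays open here and was not tested for this comparison.

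**Figure D1:**
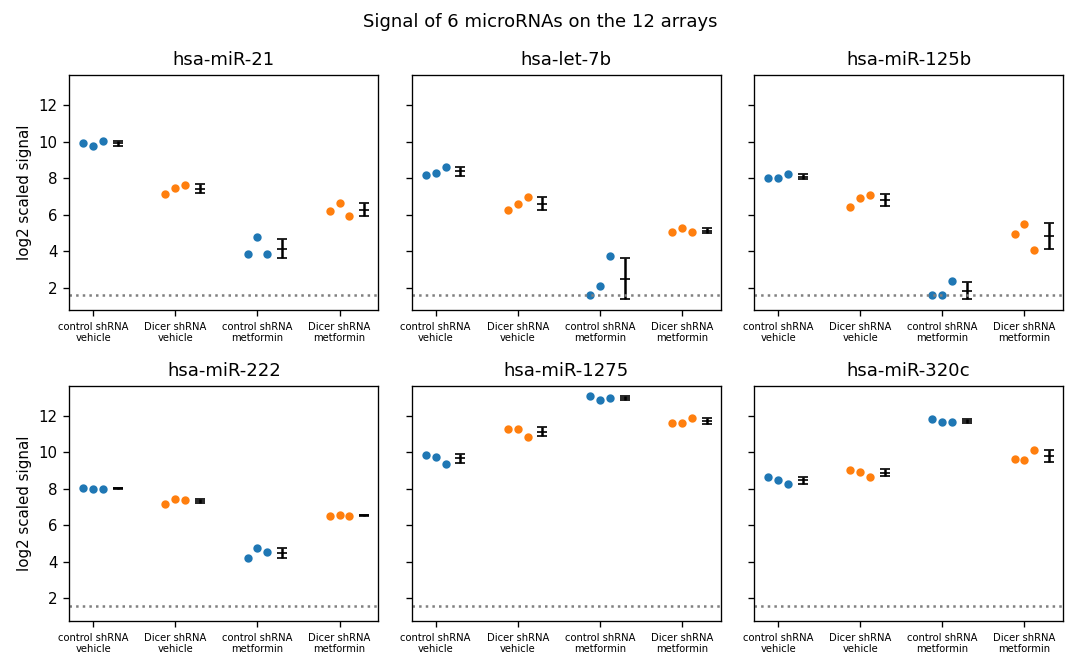
Log2 scaled signal (vertical axis) of 6 microRNAs in the 4 groups (horizontal axis). Points are the 3 arrays of a group, bars are the mean ± SD, and the dotted line is the detection floor of 1.59. miR-21, let-7b, miR-125b and miR-222 were lowest in control shRNA cells with metformin, where miR-1275 and miR-320c were highest.

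The same comparison was made between the metformin-treated lines. There, several abundant microRNAs were higher in Dicer shRNA cells than in control shRNA cells. miR-29a, whose family targets collagen and DNA methyltransferase mRNAs, rose by 3.25 ± 0.18, miR-125b by 3.01 ± 0.34, let-7b by 2.63 ± 0.45, miR-100 by 2.55 ± 0.27, miR-25 by 2.48 ± 0.17 and miR-221 by 2.33 ± 0.30. miR-342-3p was at least 4.88-fold and miR-130b at least 4.83-fold higher. miR-1826, miR-1246, miR-21, miR-24 and miR-222 rose by 2.05 to 2.29, miR-21 by 2.12 ± 0.27. The floor limits the values of miR-29a, miR-125b and miR-25, detected on 1 of 3 control shRNA arrays, and of let-7b and miR-1246, detected on 2. Among the lower ones were passenger strands, marked with an asterisk. miR-10b* was at least 4.51-fold lower, miR-129* at least 3.61-fold, miR-1306 at least 3.36-fold, miR-486-5p at least 3.28-fold and miR-602 at least 2.89-fold. miR-491-3p was at least 3.80-fold and miR-609 at least 3.31-fold lower, with all Dicer shRNA arrays at the floor. miR-320c fell by 1.92 ± 0.17, and miR-425* (1.77 ± 0.17) and miR-664 (1.64 ± 0.37) by values that the floor limits, since 1 of 3 Dicer shRNA arrays lay above it. miR-1229 and miR-129-3p, the latter detected on 2 of 3, fell by 1.49 to 1.53. let-7a, miR-103, miR-107 and miR-34a were detected in neither group and have no fold, miR-33a fell by 1.24 ± 0.22 (1 of 3 Dicer shRNA arrays detected it), and miR-16 (-0.57 ± 0.38) did not pass.

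Under metformin 81 microRNAs passed (limma, Benjamini-Hochberg), 29 higher and 52 lower, and 19 and 24 among those detected on all 12 arrays. The count was 129 (23 higher, 106 lower) after scaling to the median, 126 with array weights, 51 (36 higher, 15 lower) after scaling to viral microRNAs, and 67 (31 higher, 36 lower) with the series matrix. Of 5 invasion-linked microRNAs 3 rose (median 2.05) and miR-155 fell by 0.98, and 4 rose when adjusted over the list alone. Of 6 miR-23/27/24 members 2 rose, or 3 adjusted over the list alone (median 1.01), and both medians stayed above 0 under each scaling. Of 16 MYC-repressed microRNAs 4 rose, and of 10 miR-17/92 members 2 rose, each with a median of 0.00, and 8 and 6 members were detected in neither group. Of 23 passenger strands 9 fell (median -0.59). Camera called these 5 lists (adjusted p 0.014 to 0.049), and with an estimated correlation the adjusted p was 0.37 to 0.58. The median change was 1.95 for the hur control features, 3 of 4 higher, and -0.49 for the viral probes, 6 of 10 lower.

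**Figure D2:**
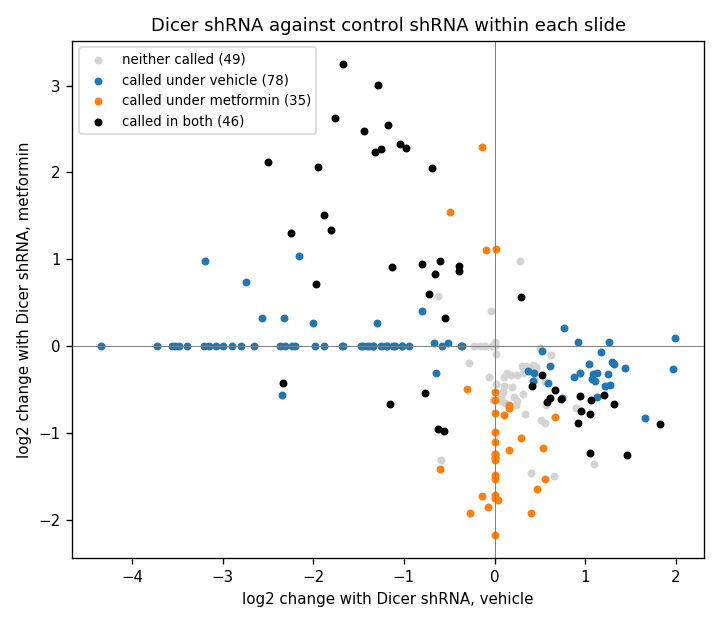
Log2 change with Dicer shRNA under vehicle (horizontal axis) and under metformin (vertical axis), 1 point per microRNA, coloured by which comparison passed. Of the 46 called in both, 40 changed in opposite directions.

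Across microRNAs, which are not independent replicates, the knockdown changes on the 2 slides had a Pearson r of -0.41 (Spearman -0.54), and -0.58 over those detected on all 12 arrays. Of 46 microRNAs called in both, 24 were lower under vehicle and higher under metformin, and 16 were higher and then lower, against about 11 each for independent lists. The 6 with one direction were miR-1260, miR-1274b, miR-155, miR-205 and miR-720, all lower, and miR-494, which was higher. They were chosen after their values were seen. Averaged over both slides, with slide as the block, 106 microRNAs passed (limma), 32 higher and 74 lower. miR-19a fell by 2.17 ± 0.07, miR-103 by 1.86 ± 0.22, let-7a by 1.78 ± 0.28, miR-29b by 1.76 ± 0.08 and let-7i by 1.74 ± 0.12, and miR-106b, miR-17, miR-27a, let-7f, miR-107, miR-16 and miR-130a fell by 1.45 to 1.69. Except miR-16, none of these 12 was detected on a metformin array, so each average is the slide 1 change divided by 2 and is set by the floor. miR-1826 rose by 1.08 ± 0.20, miR-520e by 1.04 ± 0.22, miR-125b by 0.86 ± 0.24, miR-557 by 0.85 ± 0.17 and miR-29a by 0.79 ± 0.13, while miR-100, miR-222, miR-520b, miR-342-3p, miR-221, miR-371-5p and miR-181b rose by 0.57 to 0.68. miR-557, miR-520e and miR-371-5p on slide 1, and miR-125b, miR-29a and miR-342-3p on slide 2, had control shRNA arrays at the floor. With an offset of 16 in place of the floor, the miR-29a value was -0.019. miR-33a fell by 0.61 ± 0.16 and miR-34a, again not detected on slide 2, by 0.60 ± 0.18, while miR-21 averaged -0.19 ± 0.19 and did not pass. The split was 56 and 47 after quantile normalization, 4 and 129 after scaling to the median, 55 and 56 after scaling to the reclassified entries, and 15 and 82 after scaling to viral microRNAs. Camera called 0 of the 10 lists (3 at an unadjusted p under 0.05), and fry, which tests each list alone, called 8.

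The second question was what metformin did in control shRNA cells. MicroRNAs of the same canonical families were far lower on the metformin arrays. miR-21 fell by 5.76 ± 0.27, or 54.2-fold, and was detected on all arrays of both groups. miR-24 fell by 5.11 ± 0.25 and miR-222, which targets the cell-cycle inhibitor p27, by 3.52 ± 0.13. miR-19b was at least 94.0-fold lower, miR-27a at least 72.2-fold, miR-15b at least 67.4-fold, miR-23b at least 47.4-fold, miR-146a at least 45.6-fold, miR-27b at least 39.1-fold and let-7c at least 36.5-fold. miR-29a (-6.27 ± 0.18) and miR-125b (-6.24 ± 0.34) remained detected on 1 metformin array each, and let-7b (-5.88 ± 0.45) on 2. let-7a was at least 25.5-fold lower, miR-103 at least 18.4-fold, miR-107 at least 7.95-fold and miR-34a at least 2.30-fold, and miR-16, detected on 1 of 3 metformin arrays, fell by 1.77 ± 0.38.

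The higher microRNAs rose by less. miR-370, which targets a carnitine palmitoyltransferase, rose by 3.35 ± 0.24, miR-1275 by 3.29 ± 0.16 and miR-320c by 3.24 ± 0.17. miR-630, miR-198, miR-557, miR-422a, miR-133a and miR-18b* rose by 2.47 to 2.71. The floor limits miR-557, miR-422a and miR-18b*, above it on 1 of 3 vehicle arrays, and miR-370 and miR-133a, above it on 2. miR-583 was at least 6.20-fold, miR-625* at least 5.58-fold and miR-708 at least 5.34-fold higher, with all vehicle arrays at the floor. miR-33a, a microRNA within a sterol regulator gene, was at least 2.84-fold higher (adjusted p 9.5e-05, limma). In total 183 of 208 passed (limma, Benjamini-Hochberg), 99 higher and 84 lower, and 77 of these calls involve a group with all arrays at the floor. Of the 98 detected on all 12 arrays, 61 were higher and 25 lower. After scaling to viral microRNAs the split was 36 higher and 124 lower.

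All 6 let-7 members (median -4.07), all 10 of miR-17/92 (median -3.80), all 5 of the group of miR-103, miR-107 and miR-15/16 (median -2.99) and 15 of 16 MYC-repressed microRNAs (median -2.07) fell. Of 6 miR-23/27/24 members 5 fell (median -5.20), and of 5 invasion-linked microRNAs 4 fell while miR-155 rose by 0.31. With undetected members at their bounds these medians were the same. The median of each of the 6 lists stayed below 0 under each scaling. Of 16 microprocessor-independent microRNAs 13 rose (median 1.16), and of 23 passenger strands 16 rose and 2 fell (median 1.10). After scaling to viral microRNAs these medians were -0.29 and -0.28. Of 6 metabolic microRNAs, miR-370 and miR-33a rose and 4 fell. Of 5 reclassified entries, miR-1274b and miR-923 rose and miR-1274a and miR-1308 fell. Adjusted over the list alone, each count was the same except for passenger strands, 15 higher. Camera called 8 lists, all but the metabolic and reclassified ones (adjusted p 9.7e-05 to 0.046), and with an estimated correlation the adjusted p was 0.24 to 0.37. The hur control features fell with the canonical lists, by a median of 3.84, all 4 lower. The viral probes rose with the other lists, by a median of 1.38, and all 10 were higher.

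**Figure D3:**
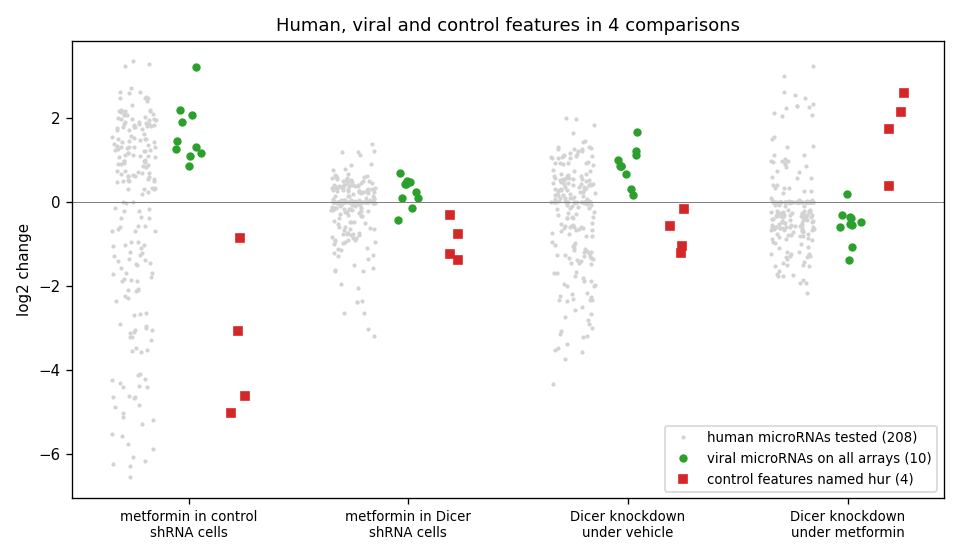
Log2 change (vertical axis) in 4 comparisons (horizontal axis) of the 208 human microRNAs tested, the 10 viral probes detected on all arrays and the 4 control features named hur, 1 point each. In metformin-treated control shRNA cells the viral median was 1.38 and the hur median -3.84, and both signs turned between the knockdown comparisons.

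In Dicer shRNA cells metformin arrays differed less from vehicle arrays. miR-15b fell by 3.18 ± 0.27, miR-27b by 2.64 ± 0.25, miR-19b by 2.38 ± 0.42, miR-23b by 2.37 ± 0.38, miR-93 by 2.35 ± 0.25, miR-146a by 2.04 ± 0.29 and miR-125b by 1.95 ± 0.34. miR-27a was at least 8.16-fold lower, miR-26a at least 6.28-fold and miR-125a-5p at least 3.05-fold. The floor limits miR-15b, miR-27b and miR-93, detected on 1 of 3 metformin arrays, and miR-19b, miR-23b and miR-146a, detected on 2. miR-140-3p (detected on 1) and let-7c fell by 1.64, miR-21 by 1.15 ± 0.27 and miR-222 by 0.78 ± 0.13. miR-133a, a muscle microRNA detected on 2 of 3 vehicle arrays, rose by 1.37 ± 0.32, miR-198 by 1.20 ± 0.27, miR-320c by 0.92 ± 0.17 and miR-1274b by 0.78 ± 0.17. miR-1249, miR-1228, miR-1275, miR-1207-5p, miR-1202, miR-191*, miR-1225-5p and miR-1234 rose by 0.42 to 0.66. With the series matrix, miR-1202, miR-1207-5p, miR-1225-5p and miR-1275 were below 0 without a call, as was miR-1202 after quantile normalization. let-7a (-1.11 ± 0.40, adjusted p 0.068, limma), miR-103 (-0.47 ± 0.31) and miR-33a (0.26 ± 0.22) did not pass, and miR-107, miR-34a and miR-16 were detected in neither group.

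Of 208, 51 passed (limma), 13 higher and 38 lower. With 1 array left out, 4 (without replicate 3 of Dicer shRNA with metformin), 5 and 6 (without replicates 3 and 2 of Dicer shRNA with vehicle), 22 (without replicate 3 of control shRNA with vehicle) or 26 (without replicate 1 of Dicer shRNA with vehicle) were higher. The count was 33 with only the groups compared, 82 with array weights, 33 without replicate 2 of Dicer shRNA with vehicle and 32 without replicate 3 of Dicer shRNA with metformin. The split was 33 and 25 after quantile normalization, 34 and 12 with the series matrix, 6 and 44 with no scaling, 4 and 42 after scaling to the reclassified entries, and 7 and 42 after scaling to viral microRNAs. Of 6 miR-23/27/24 members 5 fell (median -1.74), of 5 invasion-linked 4 fell (median -0.99), of 16 MYC-repressed 5 fell, or 6 adjusted over the list alone, and of 10 miR-17/92 members 4 fell, or 5 adjusted over the list alone. These medians stayed below 0 under each scaling. Camera called these 4 lists and, as higher, the microprocessor-independent (3 of 16 rose) and passenger strand (2 of 23 rose) lists (adjusted p 0.00084 to 0.036), and with an estimated correlation the adjusted p was 0.32 to 0.48. Adjusted over the list alone, 0 passenger strands passed. The hur median was -1.0, 3 of 4 lower, and the viral median 0.34, 1 of 10 higher.

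The third question was whether metformin changes differed between the lines. The interaction passed for 159 of 208 microRNAs (limma), 77 with a higher and 82 with a lower value in Dicer shRNA cells, and an additive slide effect cancels in it. For 59 microRNAs both groups of a slide or of a line lay at the floor, so the value repeats a single other difference and decides nothing about the response, and 38 of the 77 higher and 13 of the 82 lower ones are of this kind. Of the 118 above the floor on at least 1 array of each group, 27 were higher and 56 lower. For the other 31, of which 12 were higher and 13 lower, 1 or more groups lay wholly at the floor, which alone would make the value a bound in size. It is a bound only for let-7c, miR-130b, miR-210, miR-342-3p and miR-583. In the rest, some arrays of another group also lay at the floor, which acts the other way. The difference was 4.92 ± 0.25 for miR-29a, 4.62 ± 0.38 for miR-21, 4.39 ± 0.63 for let-7b and 4.29 ± 0.49 for miR-125b, and lay between 3.56 and 4.01 for miR-24, miR-25, miR-100 and miR-1246. The floor limits miR-29a, miR-125b and miR-25, above it on 1 of 3 metformin arrays of control shRNA cells, and let-7b and miR-1246, above it on 2. The difference was 4.17 for miR-19b, which is not a bound, since all control shRNA and some Dicer shRNA arrays with metformin lay at the floor. The values of miR-19a (4.34 ± 0.13), miR-103 (3.73 ± 0.44), let-7a (3.56 ± 0.56), miR-107 (2.99 ± 0.18) and miR-34a (1.20 ± 0.37) repeat their vehicle knockdown falls. It was -2.72 ± 0.34 for miR-370 and -2.71 ± 0.23 for miR-1275, and between -2.32 and -1.98 for miR-320c, miR-630, miR-557, miR-1183 and miR-1181. The floor limits miR-557, above it on 1 of 3 vehicle arrays of control shRNA cells, and miR-370, above it on 2. It also limits miR-1183, above it on 2 of 3 arrays in each group but control shRNA with metformin. The difference was a bound for miR-583 (-2.49). For miR-708 (-2.46), miR-664 (-2.11) and miR-1229 (-2.09) some Dicer shRNA vehicle arrays also lay at the floor, so the value is not a bound. For miR-10b* (-2.17) both vehicle groups lay at the floor. Among microRNAs detected on all 12 arrays 70 of 98 passed, 21 higher and 49 lower. After scaling to viral microRNAs the split was 115 and 20. By list, leaving out members whose value repeats another difference, 2 of 2 let-7 members, 4 of 4 of miR-17/92, 1 of 1 of the group of miR-103, 7 of 7 MYC-repressed, 4 of 5 miR-23/27/24 and 4 of 5 invasion-linked microRNAs had a higher value. The members left out number 4, 6, 4, 9, 1 and 0. Of 16 microprocessor-independent microRNAs 11, and of 23 passenger strands 13, had a lower value (medians -0.85 and -0.82, but 0.23 and 0.57 after scaling to viral microRNAs), though 4 of these passenger strands repeat another difference. Adjusted over the list alone, the counts over all members were the same except for passenger strands, 12 lower. Camera called these 8 lists over all members, those at the floor included (adjusted p 6.5e-05 to 0.048), and with an estimated correlation the adjusted p was 0.23 to 0.41. The hur median was 2.84 and the viral median -1.32. Across microRNAs the metformin changes in the 2 lines correlated (Pearson r 0.83, Spearman 0.80), on different arrays but the same slides, and all 51 microRNAs called in both had one direction.

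Overall signal before scaling, the log2 75th percentile over the 98 microRNAs, differed by -0.257 between metformin and vehicle (exact two-sided permutation p 0.015 within lines, 400 arrangements, smallest possible 0.005). Without replicate 1 of control shRNA cells with metformin, which also changes the microRNAs detected on all arrays, it was -0.450 (exact permutation p 0.01). Within control shRNA cells it was -0.37 (exact permutation p 0.1) and within Dicer shRNA cells -0.14 (exact permutation p 0.3), where 3 against 3 cannot go below 0.1. The sign was positive for the summed signal (0.208, exact permutation p 0.095). Without miR-923, in a test that was added, the summed signal differed by 0.190 (exact permutation p 0.02), so the direction depends on the measure. Dicer minus control shRNA was -0.038 (exact permutation p 0.5 within slides), and 0.370 (exact permutation p 0.015) with the median in place of the percentile. For the summed signal without miR-923 it was -0.249 (exact permutation p 0.01).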

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

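The tests of the swapped labels, the floor, the RNA composition, the additive slide effect, Dicer processing and the control features were chosen after the result was seen.

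Metformin changes that differed between the lines stand out here, by the test of the interaction itself (Dicer minus control shRNA cells, log2). It called 159 of 208 microRNAs. The values of named microRNAs with a higher difference were miR-181b 1.10, miR-34a 1.20, miR-125a-5p 1.45, miR-140-3p 1.56, miR-16 1.77, miR-93 2.27, miR-26a 2.36, miR-1826 2.43, miR-27b 2.65, miR-222 2.74, miR-15b 2.89, miR-130a 2.90, miR-107 2.99, let-7f 3.08, miR-27a 3.15, miR-23b 3.19, miR-17 3.20, miR-342-3p 3.26, miR-221 3.38, miR-106b 3.39, miR-146a 3.47, let-7i 3.48, miR-130b 3.52, miR-29b 3.53, let-7c 3.55, miR-1246 3.56, let-7a 3.56, miR-103 3.73, miR-100 3.73, miR-25 3.91, miR-24 4.01, miR-19b 4.17, miR-125b 4.29, miR-19a 4.34, let-7b 4.39, miR-21 4.62 and miR-29a 4.92. For miR-34a, miR-125a-5p, miR-26a, miR-130a, miR-107, let-7f, miR-27a, miR-17, miR-106b, let-7i, miR-29b, let-7a, miR-103 and miR-19a no metformin array gave a detected signal, so these values repeat the vehicle knockdown, and for miR-16, at the floor in Dicer shRNA cells, the value repeats the fall in control shRNA cells. Those of let-7c, miR-130b and miR-342-3p are bounds, at least of this size, with 1 group at the floor. The same group lay at the floor for miR-140-3p, miR-146a, miR-15b, miR-19b, miR-23b, miR-27b and miR-93. For these, some Dicer shRNA arrays with metformin also lay at the floor, which acts the other way, so their values are not bounds. Some control shRNA arrays with metformin lay at the floor for miR-1246, miR-25, miR-125b, let-7b and miR-29a, which limits their values.

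The values of those with a lower difference were miR-370 -2.72, miR-1275 -2.71, miR-583 -2.49, miR-708 -2.46, miR-320c -2.32, miR-630 -2.29, miR-557 -2.23, miR-10b* -2.17, miR-1183 -2.15, miR-664 -2.11, miR-1229 -2.09, miR-1181 -1.98, miR-520e -1.90, miR-425* -1.81, miR-129* -1.78, miR-1306 -1.75, miR-671-5p -1.73, miR-486-5p -1.72, miR-371-5p -1.69, miR-491-3p -1.66, miR-609 -1.59, miR-1226* -1.57, miR-602 -1.53, miR-572 -1.52, miR-129-3p -1.49, miR-564 -1.48, miR-198 -1.41, miR-625* -1.35, miR-33a -1.25, miR-1249 -1.23, miR-1207-5p -1.23, miR-520b -1.22, miR-1228 -1.18, miR-133a -1.11, miR-191* -0.84, miR-1202 -0.75, miR-1234 -0.65 and miR-1225-5p -0.58. The miR-33a value belongs equally to miR-33b*, which has the same signals. For miR-10b*, miR-129*, miR-129-3p, miR-1306, miR-486-5p and miR-602 both groups of a slide or of a line lay at the floor, so the value repeats a single other difference. That of miR-583 is a bound in size. A group also lay at the floor for miR-1229, miR-33a, miR-425*, miR-491-3p, miR-609, miR-625*, miR-664 and miR-708. For these, some Dicer shRNA vehicle arrays lay at the floor too, which acts the other way, so their values are not bounds. Some vehicle arrays lay at the floor for miR-370, miR-557, miR-1183, miR-520e, miR-371-5p and miR-133a, which limits their values. Signal in data outside the human microRNAs was present too, since 10 of 88 viral microRNA probes were detected on all 12 arrays.

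Of 46 microRNAs called in both knockdown comparisons, 24 were lower on slide 1 and higher on slide 2 and 16 the reverse, while most let-7 and miR-17/92 members did not pass on slide 2. The detection floor alone is argued against, since among the 98 microRNAs detected on all 12 arrays 71.4%, 70 of them, had a called interaction. Exchanged labels of the 2 metformin groups, whose source names are the ones that disagree with their titles, could turn the direction. Across 25 microRNAs with a mean metformin change within 0.5 log2 of 0 the 2 knockdown changes had r = 0.238. It was 0.0629 to 0.497 with 1 array left out and 0.310 with a limit of 0.25, which decides neither way. Along the leading pattern between groups, control and Dicer shRNA lay at 9.51 and 2.16 with vehicle and at -9.45 and -2.22 with metformin. Exchanged labels would give the knockdown one direction there. The second principal component held the lines apart as labelled (control shRNA -6.13 to -2.52, Dicer shRNA 2.93 to 5.50). The 2 control shRNA groups are also the ends of the first component, with the 2 Dicer shRNA groups between them. The second component therefore cannot tell line from place along the first, and the labels stay undecided. RNA composition that varies from sample to sample also stays open, with a size of correlation of 0.506 between the leading deviation within groups and the pattern between groups (0.408 to 0.694 with 1 group left out). A biological difference in how the lines respond to metformin is named by the design, stays open and was not tested apart from these.

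In control shRNA cells canonical microRNAs were far lower on the metformin arrays. With the groups as labelled, an additive slide effect as the whole change is argued against by a slope of 0.229 (0.193 to 0.259 with 1 array left out). This is the slope of the change in Dicer shRNA cells on that in control shRNA cells. It was not computed with the labels of the 2 metformin groups exchanged, so the argument holds only if the labels are right. A slide effect that acts unevenly also stays open. Lower Dicer processing stays open: 2 of 5 reclassified entries were called lower, but the Dicer shRNA lowers 3 of 5 such entries under vehicle, so their fall decides nothing, and the Dicer mRNA was not measured. A loss of signal shared with the hur control features could also account for the fall, as these 4 features fell by a median of 3.84 (value -3.84, range -5.03 to -0.86) with none higher. Before scaling, the summed human signal without miR-923 was 28771 ± 1801 (SD, n = 3) with vehicle and 36248 ± 2143 (SD, n = 3) with metformin. Bright microRNAs that rose together with the viral probes weigh heavily in this sum. Among them is miR-1275, at log2 9.37 to 9.86 with vehicle and 12.8 to 13.1 with metformin in control shRNA cells. Unspecific signal could raise the sum while small RNA is lost, so the sum decides nothing about such a loss. What the hur features detect is not given in the sources used here. Whether metformin, RNA quality or the slide lies behind a loss cannot be told apart.

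The microRNAs higher on the metformin arrays of control shRNA cells rose together with probes for viral microRNAs. If unspecific hybridization lay behind them, viral probes would rise alike, and their median change was 1.38 (0.86 to 3.21) against 1.56 for the 99 human microRNAs called higher. The test was set before the result was seen and could have come out the other way, so unspecific signal or a shift of the scaling may account for part of the rise. After scaling to viral microRNAs 36 were higher and 124 lower. Regulation of these microRNAs by metformin stays open and was not tested apart from it.

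Other splits of the arrays were counted for each comparison. Splits of 3 against 3 number 10, too few for a share under 0.05, and the real split was 1 of 10 with as many calls for metformin in control shRNA cells (183, highest other 0), metformin in Dicer shRNA cells (51, highest other 1), the knockdown under vehicle (124, highest other 3) and the knockdown under metformin (81, highest other 2). For the knockdown over both slides 1 of 100 splits within slides, the real one, called as many (106, highest other 94). These 100 leave out the split that turns the labels of 1 slide, which equals the interaction and so calls 159. The share of 1 in 100 lies under the limit of 0.05 set beforehand. The split left out calls more than the real one, so chance is not called excluded there. For the interaction 9 of 100 splits, the real one included, called as many (159, highest other 180), so by this count chance is not excluded. This follows from the structure of the samples: the 7 splits that kept the control shRNA arrays alone in their real groups called 162 to 180, and the 1 that kept both lines together with the labels of 1 line turned called 172. The 6 that kept the Dicer shRNA arrays alone called 0, and the 85 others called 0 or 1.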

How the results depend on the processing

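Scaling to viral microRNAs was chosen after seeing the data. Of 2586 values of named microRNAs under other settings, 2460 kept direction and call, or passed in neither setting, where the sign was not compared. Another 116 lost the call, 3 gained it and 7 changed sign with a call in at least 1 setting. With 1 array left out, 2091 of 2148 were the same by this rule, 56 lost the call and 1 gained it. The 7 that changed sign were, for metformin in Dicer shRNA cells, miR-1202 (-0.055 after quantile normalization, -0.154 with the series matrix), miR-1207-5p (-0.283), miR-1225-5p (-0.061) and miR-1275 (-0.174) with the series matrix, for the knockdown under vehicle miR-222 (0.118 after quantile normalization), and for both slides miR-29a (-0.019 with an offset of 16). The cause was not tested. Of 115 counts 93 stayed within 1.5 times. In these values and counts the percentile over all human names stands as a separate setting, though it equals no scaling. Of 210 list results 164 were the same by the rule above, 44 lost the call and 2 gained it.

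With microRNAs detected on all 12 arrays alone, where fewer were tested, counts were 86 (metformin in control shRNA cells), 28 (in Dicer shRNA cells), 72 (interaction), 64 (knockdown under vehicle), 44 (under metformin) and 27 (both slides), and lists called 3, 1, 2, 2 and 2 in the first 5. With an estimated correlation camera called 0 lists in each comparison (1 at an unadjusted p under 0.05 in 4 of them, 0 in the knockdown under metformin and over both slides), against 8, 6, 8, 7 and 5 in the first 5 with the preset one, and fry called 6 to 9. With no scaling 2 lists were called for both slides. The knockdown under metformin gave 129 calls with the median, 126 with array weights and 51 after scaling to viral microRNAs. Metformin in Dicer shRNA cells gave 33 with the groups compared alone, which also tests 174 microRNAs, and 82 with array weights. With 1 array left out, counts were 175 to 189, 32 to 72, 143 to 165, 113 to 130, 62 to 101 and 89 to 115 in the order above. Metformin in Dicer shRNA cells had 33 without replicate 2 of Dicer shRNA with vehicle and 32 without replicate 3 of Dicer shRNA with metformin. Overall signal with metformin was -0.133 with the median, 0.208 summed and 0.095 with the series matrix, and -0.450 to -0.229 with 1 array left out. With the knockdown it was 0.370 with the median, and -0.180 to -0.010 with 1 array left out. The percentile over all human names falls on the value for undetected ones and gives no overall signal.

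A block by replicate number gave 182, 47, 159, 124, 83 and 102 calls, and 7 of 18 pairs with one number correlated above 0.1 (-0.18 to 0.32), so the numbers are not taken as pairs. Signal near the floor limits the microRNAs detected in some groups alone. Their spread is zero where no array detected them, and their errors are understated.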

Other observations

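The tests of the number of detected microRNAs and of the control features were chosen after the data were seen.

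Lists with fewer than 3 tested members have single values. miR-223 and miR-486-5p, both abundant in blood cells, were at least 2.44-fold and 3.28-fold higher on the metformin arrays of control shRNA cells, since no vehicle array detected them. The muscle microRNA miR-133b was at least 2.36-fold higher and miR-133a, detected on 2 of 3 vehicle arrays, rose by 2.49 ± 0.32. In vehicle-treated cells the knockdown change of miR-133a was not called, and the 3 others were detected in neither group. No member of the miR-200 family, which holds epithelial identity, could be tested, and miR-200c was detected on 0 of 12 arrays. Of the p53-linked list miR-107 and miR-34a were tested, and both were detected on the arrays of vehicle-treated control shRNA cells alone.

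The reclassified entries, most of them now read as tRNA or rRNA fragments, moved apart. With Dicer shRNA, miR-720 changed by -1.16 ± 0.12 under vehicle and -0.67 ± 0.12 under metformin, and miR-1274b by -0.62 ± 0.17 and -0.95 ± 0.17. miR-923 changed by 0.53 ± 0.09 under vehicle and -0.34 ± 0.09 under metformin, miR-1308 by -0.49 ± 0.20 (not called) and 1.54 ± 0.20, and miR-1274a by -0.73 ± 0.16 and 0.60 ± 0.16.

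The viral probe kshv-miR-K12-3 was as bright as rank 14 among human microRNAs, with a mean signal of 264 ± 33.1 (SD, n = 3) in control shRNA cells with vehicle, 548 ± 46.4 in Dicer shRNA cells with vehicle, 936 ± 128 in control shRNA cells with metformin and 672 ± 91.4 in Dicer shRNA cells with metformin. The control feature mr_1 changed by -3.19 ± 0.18 with metformin in control shRNA cells, -0.80 ± 0.18 with Dicer shRNA under vehicle and 1.57 ± 0.18 under metformin. The bright corner feature changed by 0.63 ± 0.25 (adjusted p 0.0195, limma) with metformin in control shRNA cells and by 0.42 ± 0.25 with Dicer shRNA under vehicle (not called).

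The first principal component of the log2 signals held 82.3% of the variance and the second 9.73%. The number of human microRNAs detected differed by -24.8 between metformin and vehicle (exact permutation p 0.01 within lines) and by -21.5 between Dicer and control shRNA (exact permutation p 0.02 within slides).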
